A study of Mus musculus with 4 samples.

How the data were processed

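RNA was sequenced from inflamed distal colon of C57BL/6 mice aged 8 weeks, with 2 wild-type and 2 Elf4 knockout samples, at day 6 of treatment with 3% DSS. Per the labels' protocols, RNA was extracted with Trizol from washed, frozen colon, and libraries were made with a Vazyme mRNA kit for Illumina sequencing. Whether the kit kept strand is not given in the sources used here. Bowtie 0.12.2, Cufflinks 2.2.1 and the genome build mm8 are named in the submitters' processing notes, without their roles. The labels do not say whether the 2 samples of a genotype came from 2 animals.

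The deposited table gives, per the file headers, 1 FPKM value (fragments scaled by transcript length and by mapped fragments) per gene and genotype. The authors combined both samples of a genotype in that value, and how they did so is not given in the sources used here. The p-value and q-value columns come from the authors' own comparison in the deposited table. By the values, every listed gene had q of at most 0.05 and at least a 2-fold difference (relative tolerance 1e-05 on the fold), and the higher of both values was at least 0.497 FPKM. The log2 column of the deposited table held spreadsheet errors in 45 cells and was not used, and 2 gene symbols had been turned into dates. A total of 29 genes were listed at 0 in wild type and 45 in the knockout. An exact 0 can be a failed estimate, so no fold was computed against it. Counts of genes by fold kept these genes.

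Gene identifiers were compared with GENCODE M21 on GRCm38, where 4116 of 4121 were found. Of these, 100% were on the annotated chromosome and 99.98% overlapped the annotated gene. The end was equal for 76.8%, and the start for 77.5% after adding 1. The coordinates in the table are therefore on GRCm38, although the submitters' processing notes name mm8, and they are printed counting from 1. There were 3833 protein-coding genes, and 89 genes shared a locus with another listed gene.

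Without values per sample, no test between genotypes, normalization, SD or confidence interval could be computed, and the authors' call was used as deposited. Depth and counting error are unknown. Log2 ratios of knockout over wild type were computed after adding 1 to both FPKM values, which understates the change of genes with low values, and folds were computed from the FPKM values alone.

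Before the data were examined, 33 gene lists of 552 genes were fixed, of which 294 were listed. For each list with at least 3 listed genes, the listed members that were higher and lower were counted. The median log2 ratio was placed among those of 10000 random lists of the same size, drawn from the other listed genes and matched on mean expression in 10 bins. The background was thus the table itself. The share of genes that fell was compared with the same random lists, a statistic added after the data were seen. Genes were named by a rule fixed beforehand: Elf4, the 10 largest rises and 10 largest falls in log2 ratio with at least 1 FPKM in the higher group, and, in each list with at least 3 listed genes, the 3 largest changes with at least 1 FPKM in the higher group, or every listed member where there were 5 or fewer. It named 107 genes, of which 1 is not reported here, and genes named outside it are said to be chosen after their values were seen.

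The list statistic was tested on simulated data with the 4121 genes. Random lists of 5, 10 and 20 genes fell outside the central 95% by median in 5%, 5.75% and 2.5% of draws and by the share that fell in 6.25%, 5.5% and 5.25%. The ratios were shuffled over genes, so about 5% is set by construction. Lists whose genes move together were not simulated. Lists planted to move 1 way were found by median in 15%, 40% and 67.5% of draws. By the share that fell, such lists lie outside by construction, so their recovery tests nothing. Alternatives were a stricter q, a 4-fold limit, FPKM minimums of 1 and 5, unique gene names, pseudocounts of 0.1 and 0, random lists not matched on expression and centring on the table median. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.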

Results

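Gene expression was measured by RNA sequencing in inflamed distal colon of wild-type mice and of mice lacking Elf4, a transcription factor of the Ets family. The C57BL/6 mice were 8 weeks old. They received 3% dextran sulfate sodium (DSS), a polymer that injures the colon epithelium and causes colitis, and tissue was taken at day 6. Each genotype had 2 samples. The deposited table holds 1 FPKM value per genotype, so no spread between replicates, SD or n can be given for any value, and the read depth per sample is unknown. The table lists only genes that passed the authors' call. Rose and fell below therefore rest on the authors' test, and a gene outside the table is not analysed here. Unless another q is given, each gene named had q = 0.000372 in the authors' deposited table, the smallest q it holds.

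The comparison asked how loss of Elf4 altered the transcriptome of the inflamed colon. Among listed genes, epithelial genes were lower in the knockout tissue, while genes of neutrophils, macrophages, inflammatory cytokines and the extracellular matrix were mostly higher. The table listed 4121 genes, of which 1980 (48.0%) were higher and 2141 (52.0%) lower in the knockout. The median fold was 2.91 among the higher genes and 3.71 among the lower genes. With a difference of at least 4-fold, 533 genes were higher and 1011 lower. In the authors' deposited table the largest q was 0.0499971, and the smallest p, 5e-05, was shared by 2233 genes.

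Elf4 itself (ENSMUSG00000031103), at X:48411046-48463132 on the minus strand of GRCm38, fell from 16.4 FPKM in wild type to 3.51 FPKM in the knockout. This was a 4.68-fold difference, with 21.4% of the wild-type value left. Epithelial genes and the 12 listed T and NK cell markers also fell in this tissue. The share of Elf4 transcript left per cell was therefore not measured. The value per sample is not analysed here, and which part of the gene was targeted is not given in the sources used here. Of 11 other Ets family genes fixed in advance, 5 were listed, with a median log2 ratio of -1.04 at the 56.65 percentile of random lists of listed genes. Elf3 fell from 234.8 to 18.0 FPKM and Ehf from 79.0 to 5.87 FPKM, and both encode epithelial Ets factors. Spib fell from 14.7 to 6.66 FPKM (q = 0.00312 in the authors' deposited table). Ets2 rose from 58.9 to 120.9 FPKM, and Spi1, the myeloid factor PU.1, rose from 23.9 to 49.7 FPKM (q = 0.00128 in the authors' deposited table).

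Among the largest rises on the log2(FPKM + 1) scale were genes of granulocyte production and recruitment. Csf3, which encodes the granulocyte growth factor G-CSF, rose 54.5-fold from 4.78 to 260.3 FPKM. The neutrophil-attracting chemokines Cxcl2 (5:90903871-90905938) and Cxcl3 (5:90786103-90789600) rose 46.9-fold and 41.7-fold, to 522 and 146.7 FPKM. The neutrophil collagenase gene Mmp8 rose 54.0-fold to 94.1 FPKM. Ngp, a neutrophil granule gene, rose 108-fold from 0.357 to 38.5 FPKM (q = 0.000998 in the authors' deposited table). Arg1, encoding arginase, rose 49.5-fold to 67.1 FPKM. Chil3, a chitinase-like gene of macrophages, rose 30.4-fold to 260.2 FPKM, and the heme oxygenase gene Hmox1 rose 28.9-fold to 596 FPKM. The other 2 of the 10 largest rises were Igkv4-51, a kappa variable segment (3.99 to 339 FPKM), and B230307C23Rik (0.648 to 54.0 FPKM).

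Among the 10 largest falls were genes of colon epithelium. Aqp4 (18:15389394-15403684), a water channel gene, fell 111-fold from 341 to 3.07 FPKM. Gsdmc4 (15:63891264-63912297) fell 94.4-fold from 975 to 10.3 FPKM and Gsdmc2 fell 55.4-fold from 316 to 5.69 FPKM. Dmbt1, encoding a mucosal scavenger receptor protein, fell 38.8-fold from 1723 to 44.4 FPKM. Its locus in the table, 7:130162451-133124354, is wider than the annotated gene, 7:131032053-131121630, so reads of neighboring genes are not excluded and its value is uncertain. Hao2, a peroxisomal oxidase gene, fell 81.2-fold to 0.827 FPKM. Ckmt1, a mitochondrial creatine kinase gene, fell 32.0-fold to 38.4 FPKM, and Spink4, a goblet cell gene, fell 31.0-fold to 65.5 FPKM. Of the 3 immunoglobulin segments among these falls, Igkv4-81 went from 87.2 FPKM to a listed 0. Igkv12-38 fell from 316 to 3.50 FPKM (q = 0.00712) and Ighv9-2 from 270.6 to 4.13 FPKM (q = 0.00384), both q from the authors' deposited table. The Gsdmc genes and the immunoglobulin segments have near-identical copies, so the split of reads between copies is uncertain.

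**Figure D1:**
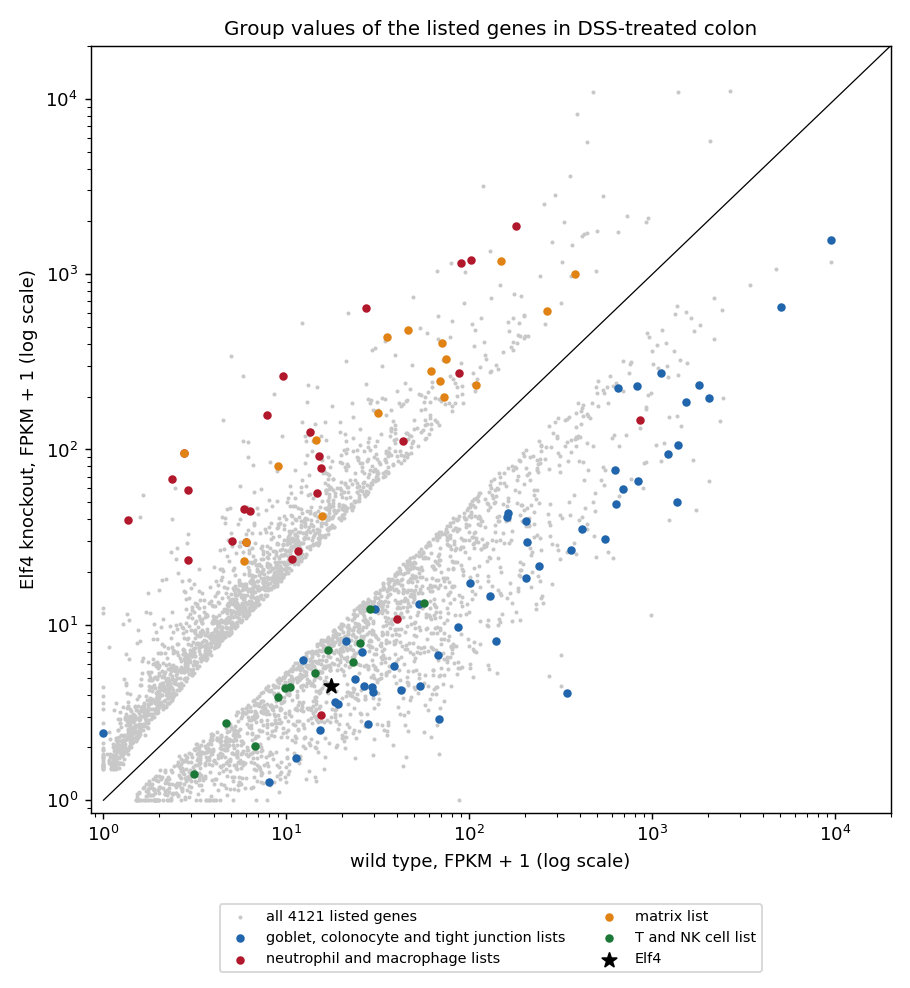
Group FPKM plus 1 of the 4121 listed genes in wild type (x axis) and Elf4 knockout (y axis), both on log scales, with 1 value per group and no error; colors mark members of gene lists, the star marks Elf4 and the line marks equal values. Goblet, colonocyte and tight junction genes lie below the line except for 1 gene, and matrix genes lie above it.

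Genes of mature colon epithelium fell together. Of 28 colonocyte genes fixed in advance, 20 were listed and 20 fell, with a median log2 ratio of -3.09. After Aqp4, the largest changes were in Slc5a8, a short-chain fatty acid transporter gene (67.5 to 1.91 FPKM), and Slc26a3, a chloride and bicarbonate exchanger gene (358 to 25.8 FPKM). Of 17 goblet cell and mucus genes, 15 were listed and 14 fell (median -2.70). Agr2, needed for mucin folding, fell from 1364 to 49.4 FPKM, Klk1 from 549 to 29.9 FPKM and the membrane mucin gene Muc13 from 1377 to 106 FPKM. The exception was Tff1, chosen after its values were seen, listed at 0 in wild type and 1.41 FPKM in the knockout (q = 0.00429 in the authors' deposited table). Of 17 tight junction and adhesion genes, 15 were listed and 15 fell (median -2.65). Cldn8 fell from 139 to 7.07 FPKM, Cldn3 from 410.2 to 34.1 FPKM, and Tjp3 from 53.0 to 3.46 FPKM (q = 0.00156 in the authors' deposited table). As many falls were seen in 0, 25 and 4 of 10000 random lists matched on expression for the colonocyte, goblet cell and tight junction lists. Over these lists together, 49 of 50 listed genes were lower.

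The other epithelial lists had fewer listed members or moved both ways. Of 15 crypt base and stem cell genes, 5 were listed. Prom1 fell from 137 to 33.0 FPKM, the crypt transcription factor gene Sox9 from 8.57 to 1.43 FPKM, Ephb2 from 9.31 to 2.09 FPKM and Rnf43, an inhibitor of Wnt signaling, from 4.18 to 0.990 FPKM. Smoc2 rose from 5.19 to 27.5 FPKM. Of 16 enteroendocrine and tuft cell genes, 5 were listed. The hormone genes Insl5, Pyy and Gcg fell 5.04-fold, 3.29-fold and 2.60-fold. Sst, the somatostatin gene, rose 3.55-fold from 55.9 to 198 FPKM, and Tph1, for serotonin synthesis, rose 3.43-fold (q = 0.000998 in the authors' deposited table). Of 15 fetal-like and wound epithelium genes, 8 were listed, 2 higher and 6 lower. Ereg, an EGF receptor ligand gene, rose from 52.5 to 491 FPKM, while Sprr1a fell from 48.8 to 5.21 FPKM and Krt7 from 20.3 to 2.94 FPKM. The medians of these 3 lists lay at the 5.98, 33.4 and 31.2 percentiles of the random lists.

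Of 24 antimicrobial and epithelial defence genes, 16 were listed, 11 lower and 5 higher, with a median log2 ratio of -2.43 at the 0.06 percentile. Pigr, which carries IgA across the epithelium, fell from 606 to 23.0 FPKM. The acute-phase gene Saa3 rose from 436 to 5686 FPKM and Lcn2, encoding a siderophore-binding protein, from 88.7 to 1163 FPKM. The other 3 that rose, chosen after their values were seen, were S100a8 (101.4 to 1202 FPKM), S100a9 (178 to 1888 FPKM) and Ang4 (15.9 to 46.2 FPKM, q = 0.00263 in the authors' deposited table). Of these 16 genes, 6 were also in other lists.

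Myeloid and inflammatory genes rose. Of 18 neutrophil markers, 15 were listed and 13 rose (median log2 ratio 3.23), and 5 of the 15 were also in other lists. Besides Mmp8 and Ngp, Retnlg rose from 26.3 to 643 FPKM. The 2 that fell, chosen after their values were seen, were Ly6g (854 to 145.7 FPKM) and Ltf (14.4 to 2.05 FPKM). Of 19 monocyte and macrophage markers, 11 were listed and 10 rose (median 2.35). Adgre1, Csf1r, Lyz2, Ly6c2, Ccr2, C1qa, C1qb and C1qc were not listed, so the rise covers only part of this list. The scavenger receptor gene Marco rose from 1.89 to 58.0 FPKM, and Nos2, chosen after its values were seen, fell from 39.3 to 9.75 FPKM. Of 19 inflammatory cytokine genes, 11 were listed and 9 rose (median 2.52). Il6 rose from 11.6 to 118 FPKM, while Il18, an epithelial and myeloid cytokine gene, fell from 249 to 13.6 FPKM. Ifng, chosen after its values were seen, fell from 4.51 to 0.272 FPKM (q = 0.0204 in the authors' deposited table). Of 21 chemokine genes, 15 were listed and 10 rose (median 2.15), with Cxcl1 going from 48.4 to 735 FPKM. The 5 that fell, chosen after their values were seen, were Cxcl9, Cxcl10, Ccl5, Ccl20 and Ccl28, with q = 0.0238 for Ccl20 in the authors' deposited table. The medians of these 4 lists lay above those of the random lists, at the 100 percentile. Random lists with as many rises numbered 4, 19, 205 and 495 of 10000.

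Genes of T and NK cells, antigen presentation and the interferon response fell. Of 21 T and NK cell markers, 12 were listed and 12 fell (median log2 ratio -1.24). Gzma, a cytotoxic granule protease gene, fell from 55.3 to 12.3 FPKM, the T cell receptor complex gene Cd3g from 22.1 to 5.16 FPKM and Itgae, an integrin gene of T cells within the epithelium, from 5.74 to 1.05 FPKM. Of 15 antigen presentation genes, 10 were listed and 10 fell (median -1.50). The class II regulator gene Ciita fell from 9.37 to 2.25 FPKM, H2-DMb1 from 59.98 to 14.6 FPKM, and Psmb9 from 80.1 to 19.7 FPKM (q = 0.00211 in the authors' deposited table). Psmb9 shares its locus with another listed gene. Of 29 interferon-stimulated genes, 11 were listed and 10 fell (median -1.68), including Zbp1 (225 to 54.3 FPKM) and Oas1a (61.1 to 14.6 FPKM). Ifi27l2a rose from 321 to 1173 FPKM. As many falls were seen in 0, 45 and 252 of the 10000 random lists, while the medians lay at the 9.11, 19.1 and 9.93 percentiles. In the same tissue, 38 of 38 listed genes of a pan-epithelial list, written after the table was first examined, were lower, by a median of 10.6-fold.

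Of 20 B cell and plasma cell markers, 4 were listed (median log2 ratio -1.60, at the 10.88 percentile). The B cell genes Cr2, Fcer2a and Ms4a1 fell 7.06-fold, 5.49-fold and 3.35-fold. Iglc1, a lambda constant segment, rose from 354 to 3602 FPKM, and it shares its locus with another listed gene. Of 14 mast cell and eosinophil markers, 5 were listed, at the 57.22 percentile. The mucosal mast cell proteases Mcpt1 and Mcpt2 fell from 31.7 to 3.99 FPKM and from 17.9 to 1.06 FPKM. Ccr3 rose from 0.948 to 4.85 FPKM, Kit from 7.95 to 17.7 FPKM (q = 0.00184) and Siglecf from 0.608 to 1.65 FPKM (q = 0.0418), both q from the authors' deposited table. The median of the mast cell and eosinophil list, 0.72, became -2.71 when only genes with at least 5 FPKM in the higher group were kept.

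Genes of the connective tissue, vessels and nerves of the colon wall rose. Of 23 matrix and matrix-degrading genes, 18 were listed and 18 rose (median log2 ratio 2.24). Besides Mmp8, the collagenase gene Mmp13 rose from 34.5 to 437 FPKM and the thrombospondin gene Thbs1 from 45.2 to 480.0 FPKM. Of 15 endothelial genes, 10 were listed and 10 rose (median 1.34). Selp, a leukocyte adhesion gene, rose from 10.95 to 60.5 FPKM, the lymphatic gene Lyve1 from 22.2 to 96.6 FPKM and Cdh5 from 10.1 to 39.4 FPKM. Of 16 enteric neuron and glia genes, 11 were listed and 11 rose (median 1.29), with the neuropeptide gene Vip going from 77.2 to 439 FPKM and Uchl1 from 22.8 to 72.9 FPKM. As many rises were seen in 0, 7 and 2 of the 10000 random lists. The endothelial median lay at the 98.02 percentile, but at 97.29 with a pseudocount of 0.1 and 96.58 with at least 5 FPKM, inside the central 95%. Of 14 fat tissue genes, 6 were listed and 5 rose (median 1.499, at the 97.18 percentile), among them Fabp4 (66.1 to 427 FPKM), Cfd (56.0 to 170.2 FPKM) and Cidec (7.76 to 25.15 FPKM). Pparg, chosen after its values were seen, fell from 33.7 to 11.2 FPKM. Adipoq, Lep, Plin1, Lpl, Lipe, Ucp1, Cidea and Pck1 of this list were not listed. Of 9 red blood cell genes, the 4 listed rose (median 1.95, at the 98.95 percentile), between 4.20-fold for Hba-a1 and 5.49-fold for Hba-a2 (q = 0.0141 in the authors' deposited table). Hbb-bs rose 4.60-fold and Hbb-bt 4.46-fold (q = 0.000998 for Hbb-bt in the authors' deposited table). These globin genes are near-identical pairs, so values within a pair are uncertain.

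Proliferation and mitochondrial genes fell. Of 21 cell cycle genes, 14 were listed and 14 fell (median log2 ratio -1.26), including Top2a (28.1 to 7.10 FPKM), Rrm2 (18.7 to 5.29 FPKM) and Aurka (7.71 to 1.88 FPKM). Of 17 mitochondrial and oxidative phosphorylation genes, 12 were listed and 12 fell (median -1.38). Cycs, the cytochrome c gene, fell from 152.6 to 28.3 FPKM, Cox5a from 569 to 184 FPKM and Cox7a1 from 43.3 to 1.70 FPKM (q = 0.0128 in the authors' deposited table). As many falls were seen in 0 and 17 of the 10000 random lists, while the medians lay at the 8.5 and 25.8 percentiles. The median fold was 2.93 for the cell cycle genes and 2.67 for the mitochondrial genes, beside 10.6 for the pan-epithelial genes, which also fell. Of 20 stress and hypoxia genes, 10 were listed and 9 rose (median 1.52, at the 99.55 percentile). Ier3 rose from 38.2 to 343 FPKM and Egr1 from 14.4 to 118 FPKM. Car9, chosen after its values were seen, fell from 29.9 to 5.80 FPKM.

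Of 26 drug-metabolizing enzymes and transporters, 18 were listed, 8 higher and 10 lower. Ces2a fell from 33.2 to 1.51 FPKM, Ugt2b34 from 80.8 to 5.07 FPKM and Sult1b1 from 216 to 15.4 FPKM. Of 17 peroxisome, fatty acid oxidation and ketogenesis genes, 9 were listed, 3 higher and 6 lower. Pdk4, which restrains pyruvate oxidation, rose from 1.95 to 17.0 FPKM and Angptl4 from 15.5 to 58.0 FPKM, while Cpt2, for fatty acid import into mitochondria, fell from 42.3 to 11.7 FPKM. Of 18 pancreas and small intestine genes, 5 were listed. Apob, Cela1, Lyz1 and Clps fell 12.03-fold, 5.43-fold, 2.81-fold and 2.35-fold, and Apoa1 was listed at 0 in wild type and 3.40 FPKM in the knockout. The q was 0.000998 for Lyz1 and 0.0486 for Clps in the authors' deposited table. The medians of these 3 lists lay at the 20.8, 31.5 and 12.2 percentiles of the random lists.

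Lists of neighboring tissues had few listed members. Of 15 smooth muscle genes, 1 was listed, Hspb7, which rose 6.54-fold. Of 12 skeletal muscle genes, 1 was listed, Ckm, which fell 3.14-fold (q = 0.0134 in the authors' deposited table). Hspb7 and Ckm were chosen after their values were seen. Of 16 genes of squamous epithelium, as in the anal canal, and of 5 Y-linked and X-inactivation genes, 0 were listed. Among the 28 lists with at least 3 listed genes, 13 had a median outside the central 95% of the random lists. By chance 1.4 would be reached if the genes of a list moved independently. By the share of genes that fell, 16 lists lay outside. The random lists describe these values of 2 groups and give no p-value, since genes are not replicates.

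**Figure D2:**
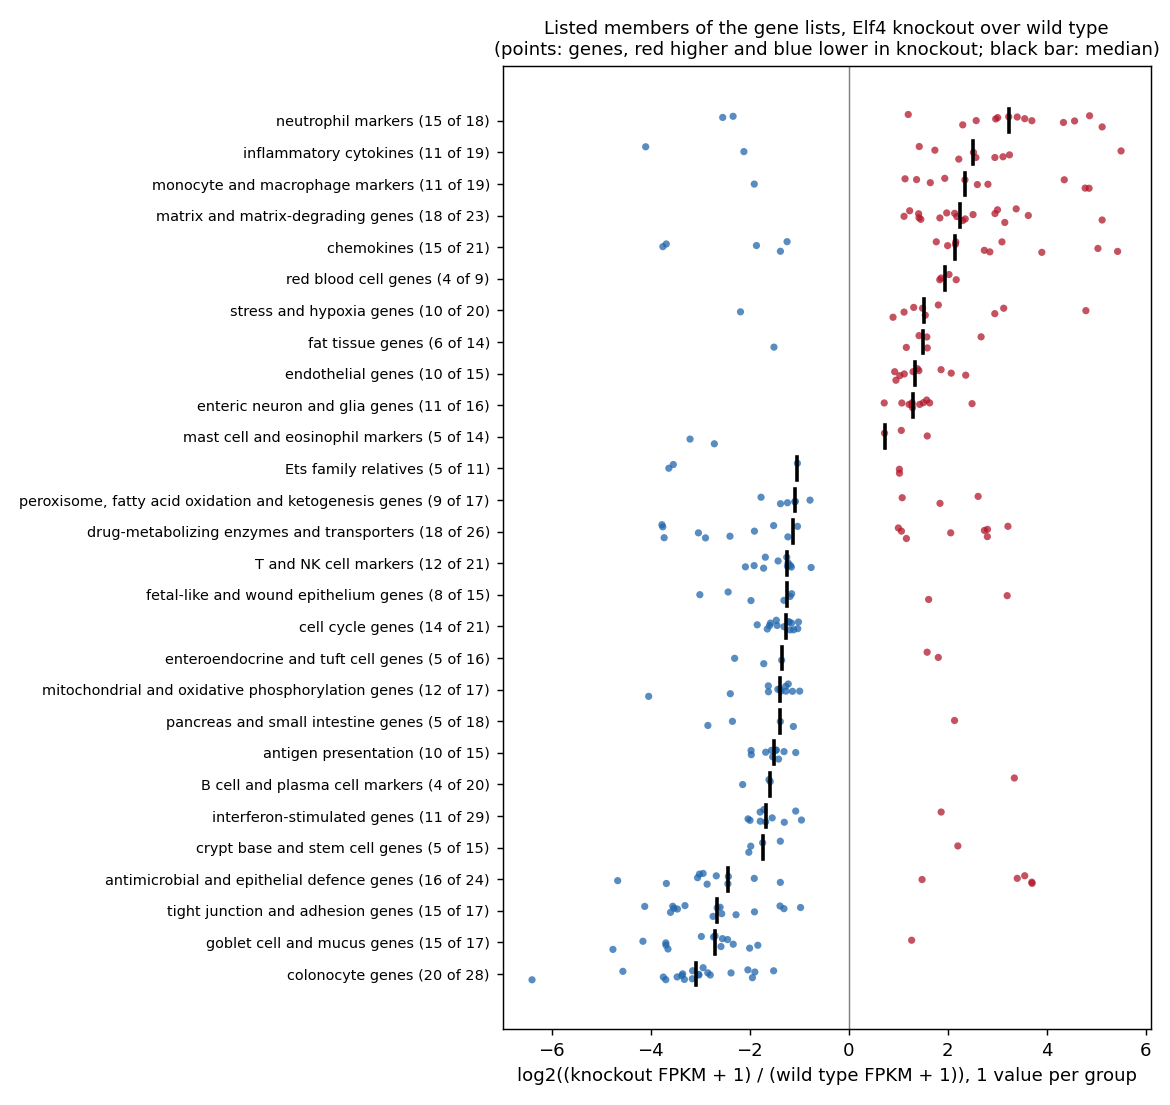
Log2 ratio of knockout over wild-type FPKM, with 1 added to both, for each listed member of the 28 gene lists with at least 3 listed genes; points are genes (red higher, blue lower in the knockout), bars are medians, and brackets give genes listed of genes fixed. Medians run from -3.09 for colonocyte genes to 3.23 for neutrophil markers.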

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

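The comparison by the share of genes that fell was chosen after the data were seen. No paired analysis was possible because the table has 1 value per group. For the same reason, another normalization, a pseudocount for the calls and leaving out each sample were not run, and how far 1 sample sets any value is unknown. With no replicate spread, a value was taken as moved when it shifted by over 1.5 times. Keeping only differences of at least 4-fold, and genes listed at 0 in 1 genotype, gave 1544 genes. Of these, 533 were higher and 1011 lower, by construction fewer than the 4121. With q of at most 0.01 there were 3271, with at least 1 FPKM 3963, with at least 5 FPKM 3195 and with unique names 4119. The log2 ratio of Elf4 was -2.19 and -2.23 with pseudocounts of 0.1 and 0. The table median was -0.76, and centring on it moved the medians of 28 lists by that amount and turned none. Of the other list medians, 111 moved by less than 1.5 times and 1 reversed: the mast cell and eosinophil median was -2.71 with at least 5 FPKM, a limit that leaves out Ccr3 and Siglecf. Of the list percentiles, 134 kept their side of the 95% bounds, and 2 came inside, both of the endothelial list (97.29 with a pseudocount of 0.1, 96.58 with at least 5 FPKM). The 4 that passed out were fat tissue (97.56 with a pseudocount of 0.1, 98.47 unmatched), interferon-stimulated genes (2.09 unmatched) and mast cells and eosinophils (2.17 with at least 5 FPKM). Lists outside the bounds numbered 13 by median, 15 without matching on expression and 16 by the share that fell. Depth is unknown, so what it limits cannot be given.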

Other observations

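The tests of a smaller epithelial share as the only change and of plasma cell number, the gene families described here, and the single genes named in this part outside the naming rule, were chosen after the values were seen. Of 46 inflammasome, caspase and gasdermin genes, 19 were listed and 17 were lower in the knockout. The median fold of the listed genes was 6.17, beside 10.6 for the pan-epithelial genes, of which 38 of 38 listed were lower. The epithelial inflammasome gene Nlrp6 went from 37.2 to 1.06 FPKM, Casp1 from 125.5 to 18.0 FPKM and Gsdmd from 194 to 38.0 FPKM, while Nlrp3 went up from 2.17 to 9.31 FPKM and Nlrp12 from 0.453 to 2.10 FPKM (q = 0.00384 for Nlrp12 in the authors' deposited table). In the interleukin-1 family and its receptors, 9 of 12 were higher and Il18, Il18bp and Il18r1 lower (q = 0.0204 for Il18bp and 0.00335 for Il18r1 in the authors' deposited table), with Il1b going from 77.6 to 261.5 FPKM and Il1a from 3.45 to 19.8 FPKM. All 8 listed prostaglandin and lipoxygenase genes were higher, led by Ptgs2, encoding cyclooxygenase-2, from 12.2 to 231 FPKM.

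Of the 4 listed metallothionein genes, for metal-binding proteins, 3 were higher. Mt1 and Mt2 went from 388 to 8174 FPKM and from 473 to 10908 FPKM, while Mt4 went from 1.32 FPKM to a listed 0 (q = 0.0370 in the authors' deposited table). All 16 listed collagen genes and all 12 listed Adamts and Adamtsl protease genes were higher. Of 10 platelet genes, 3 were listed. Ppbp, Pf4 and Itga2b were higher, with Pf4 going from 33.7 to 412 FPKM (q = 0.00792 for Itga2b in the authors' deposited table). As many rises were seen in 922 of 10000 random lists. Of 41 complex I subunit genes, 13 were listed and 13 were lower. Of 19 cytochrome c oxidase subunit genes, 11 were listed and 10 were lower. The exception, Cox6b2, went from 10.4 to 27.9 FPKM (q = 0.0321 in the authors' deposited table). The medians of these 2 families lay at the 44.3 and 20.8 percentiles of random lists. Their median folds were 2.34 and 2.89, beside 10.6 for the pan-epithelial genes. All 5 listed Akr1c genes were lower. The Akr1c genes have near-identical copies.

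Epithelial genes fell while matrix, endothelial, enteric neuron and myeloid genes rose, and 1 of 15 smooth muscle genes was listed. A smaller epithelial share of the knockout tissue may account for the epithelial part. In the pan-epithelial list, 38 of 38 listed genes (100%) were lower, by a median of 10.6-fold, among them Krt8 (2335 to 144 FPKM) and Epcam (898 to 82.8 FPKM). Their log2 ratios ran from -4.26 to -1.11, so the falls were unequal. That list was written after the table was first examined, with the fall of other epithelial genes already seen. As the only change, a smaller share is argued against for the genes given here. Alone, it would raise genes outside the epithelium by a similar factor. The quartiles of the log2 ratio were instead 2.44 to 4.02 for listed neutrophil markers and 1.05 to 1.75 for listed endothelial genes. The B cell genes Cr2, Fcer2a and Ms4a1 were lower, while Iglc1 was higher. Of the listed T and NK cell markers, 12 of 12 (100%) were lower while 10 of 10 listed endothelial genes were higher. For the T and NK cell markers, loss of T cells within the epithelium stays open. Members outside the table are not analysed here. Knockout pieces taken nearer the caecum cannot be told apart from a smaller epithelial share. Of only 3 listed posterior Hox genes, 2 (66.7%) were lower, Hoxb13 and Hoxa13 but not Hoxd9 (q = 0.000998 for Hoxa13 and 0.0324 for Hoxd9 in the authors' deposited table). Of 6 listed anterior ones, Hoxb2, Hoxb3, Hoxb4 and Hoxb5 were higher and Hoxa7 and Hoxb9 lower (q between 0.000694 and 0.0403 in the authors' deposited table). Hoxb2 and Hoxb3 share the same locus, so their values may not be separate. Hoxd9 was counted as posterior but Hoxb9, of the same number and opposite direction, as anterior. The posterior share depends on that choice and decides nothing. Epithelial loss in more severe colitis and direct effects of Elf4 stay open, untested.

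Immunoglobulin variable segments moved both ways. A change in plasma cell number alone is argued against, since 50 of 88 listed segments (56.8%) were higher and 38 lower. Summed over these segments, FPKM was 27727 in wild type and 53893 in the knockout, and 27 of 43 heavy-chain and 21 of 42 kappa segments were higher. As many rises were seen in 4 of 10000 random lists for the heavy-chain segments and in 923 for the kappa segments. The heavy-chain segments thus leaned to higher values. The annotation holds 185 heavy-chain and 160 kappa segments, and those outside the table are not in the sums, so total expression is unknown. Of the plasma cell markers fixed in advance, Jchain, Igha, Igkc, Sdc1 and Mzb1 were not listed. A net rise in plasma cells beside another change stays open. Different plasma cell clones in few animals, and reads shared between similar segments, stay open and were not tested.

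DNA of a donor strain left around the targeted locus could add differences near Elf4. Within 10 Mb on each side, 10 of 92 protein-coding genes (10.9%) were listed, at the 53.6 percentile of 151 windows of that width on X, whose median was 10%. The share was neither high nor at or below that median, so such DNA cannot be told apart from the genotype itself, and no sequence variants were analysed here.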
